A study of Mus musculus with 28 samples.

How the data were processed

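All values start from the deposited tables, which hold 1 raw read count per Ensembl gene and library in 3 tables. RNA was measured in 28 libraries of sorted Treg cells, grouped by the sample labels. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to mm10 with TopHat, counted with HTSeq and compared with edgeR. Versions, the strand setting and the filters are not stated there. Per the labels' protocols, the libraries of RISP_WT and RISP_KO were made with the Takara kit (SMART-Seq v4 and Nextera XT), and those of the chimeras and of the in vitro groups with the NEB kit (NEBNext Ultra I after poly(A) selection). Libraries held 28.4 to 50.8 M counts in the table of 3-week-old mice, 20.4 to 31.0 M in the chimera table and 2.71 to 3.45 M in vitro. The 50 most abundant genes took 11.9 to 12.9% of the counts in 3-week-old mice, 12.7 to 13.7% in chimeras and 10.4 to 12.0% in vitro. No pair of libraries was a duplicate. A further table with 11 per-sample columns was not used here, because its columns carry no sample name of the labels.

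The tables list 43430 gene IDs, of which 42462 have a symbol in the name table and 42546 are in GENCODE M21 (42455 on the same chromosome, 42411 with an overlapping interval, 34004 with the same ends within 1 base). IDs without a symbol hold 0.110 to 0.779% of the counts of a library. CPM of single libraries are relative to all counts of the library. Group means ± SD of CPM use library sizes scaled by TMM. Genes that share sequence or overlap another gene can take or lose counts, and without the strand setting this cannot be judged.

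Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Each comparison used filterByExpr by group, TMM factors and glmQLFTest, with genes called at a Benjamini-Hochberg adjusted p under 0.05. The 2 knockout comparisons were fitted in their own table, the 6 comparisons of inhibitors in 1 fit of the 12 in vitro libraries, and the difference of the knockout effects in 1 fit of 16 libraries, 9 comparisons in total. The SE of a log2 fold change is its unshrunken estimate divided by the square root of the quasi-likelihood F, and log2 fold changes use a prior count of 0.125. The labels do not state whether replicates are separate mice, so a p-value measures the spread between these libraries, which may be technical. In 3-week-old mice the sex-linked gene Ddx3y read 0.135 and 0.200 CPM in replicate 1 of RISP_WT and RISP_KO. In replicate 4 it read 99.5 and 80.9 CPM, and Xist went the other way (57.1 and 66.5 against 3.23 and 4.87 CPM). These values argue against a purely technical spread between those libraries. The common dispersion gave a coefficient of variation between libraries of 21.6% in 3-week-old mice, 20.5% in chimeras and 14.7% in vitro.

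The 47 gene lists cover Treg cell function, mitochondrial complexes and metabolism, stress responses, cell cycle and translation, chromatin, and markers of cell types. They were written from general knowledge, and with the tests, the rule for named genes and the first alternatives they were set before the data were examined. Each list with 3 or more measured genes was tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation beside it. Of 47 lists in RISP_KO, 21 were called with the preset and 1 with the estimated correlation, of 45 in RISP_Chimera_KO 19 and 0, and of 39 in vitro 19 and 8 with piericidin, 20 and 3 with 3-NPA and 24 and 10 with antimycin A.

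Genes named are Uqcrfs1, Foxp3, Il2ra, Ctla4 and Il10, the 5 largest rises and the 5 largest falls among called genes with a mean log2 CPM of at least 3 (prior count 2) whose CPM do not overlap between the 2 groups, and up to 3 called members with the smallest p of each list described (up to 2 uncalled ones where none was called). Immunoglobulin and T cell receptor variable segments, predicted genes and pseudogenes were passed over among the largest changes. Results for 2 further genes are not reported here. For the difference of knockout effects no 2 groups exist whose overlap could be read, so only the level over the 4 groups was required. Alternatives tried were DESeq2, RLE factors, no filter, a filter of 1 CPM, a 1.5-fold minimum, the replicate number as a block, fits of only the 2 groups compared, and leaving out each library. Markers of other cell types as a covariate, and leaving out 2 chimera libraries, were added later. Random draws used seed 1.

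The scripts were tested on simulated counts of the same depth and spread with 200 changed genes. There edgeR recovered 31.3% of 1.5-fold, 64.2% of 2-fold and 92.4% of 4-fold changes for RISP_KO. It recovered 37.3%, 68.7% and 84.8% for the chimeras, 31.3%, 70.1% and 93.9% for antimycin A, and 14.9%, 49.3% and 59.1% for the difference of knockout effects. False calls were 3.10%, 3.79%, 4.41% and 2.38% of the calls.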

Results

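The series measures RNA in CD4+ YFP-Foxp3+ CD25+ regulatory T (Treg) cells of mice, in 28 libraries. RISP, the Rieske iron-sulfur subunit of mitochondrial complex III encoded by Uqcrfs1, was present or knocked out in Treg cells of 3-week-old mice (RISP_WT and RISP_KO, n = 4 each) and of chimeras aged 8 to 12 weeks (RISP_Chimera_WT and RISP_Chimera_KO, n = 4 each). RISP wild-type Treg cells of 3-week-old mice were also kept in vitro untreated or with 1 µM piericidin (an inhibitor of complex I), 500 µM 3-NPA (3-nitropropionic acid, complex II) or 1 µM antimycin A (complex III), n = 3 each. Differences between groups were tested with edgeR quasi-likelihood F-tests, and adjusted p is by Benjamini-Hochberg throughout.

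Uqcrfs1 (chromosome 13, 30540308 to 30545362, mm10) was lower in every knockout library than in any control. It read 5.14 to 7.45 CPM in the 4 RISP_KO libraries against 154 to 189 CPM in the 4 RISP_WT libraries, and 4.83 to 11.3 CPM in RISP_Chimera_KO against 73.5 to 85.9 CPM in RISP_Chimera_WT. The log2 fold change was -4.83 ± 0.14 (SE, adjusted p = 2.19e-08, n = 4 per group) in 3-week-old mice and -3.60 ± 0.23 (adjusted p = 1.26e-05, n = 4 per group) in chimeras. In vitro, in RISP wild-type cells, Uqcrfs1 was not called with piericidin (-0.23 ± 0.22, adjusted p = 0.569), 3-NPA (0.13 ± 0.22, adjusted p = 0.838) or antimycin A (-0.20 ± 0.22, adjusted p = 0.609), n = 3 per group. Foxp3, which encodes the transcription factor that defines the Treg lineage, was not called in RISP_KO (0.02 ± 0.14, adjusted p = 0.959) or in RISP_Chimera_KO (0.11 ± 0.09, adjusted p = 0.637). Ctla4, an inhibitory receptor of Treg cells, was not called in RISP_KO (0.06 ± 0.15) or RISP_Chimera_KO (-0.53 ± 0.21), and neither was Il10, a suppressive cytokine (-0.89 ± 0.45 and -1.74 ± 0.82).

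**Figure D1:**
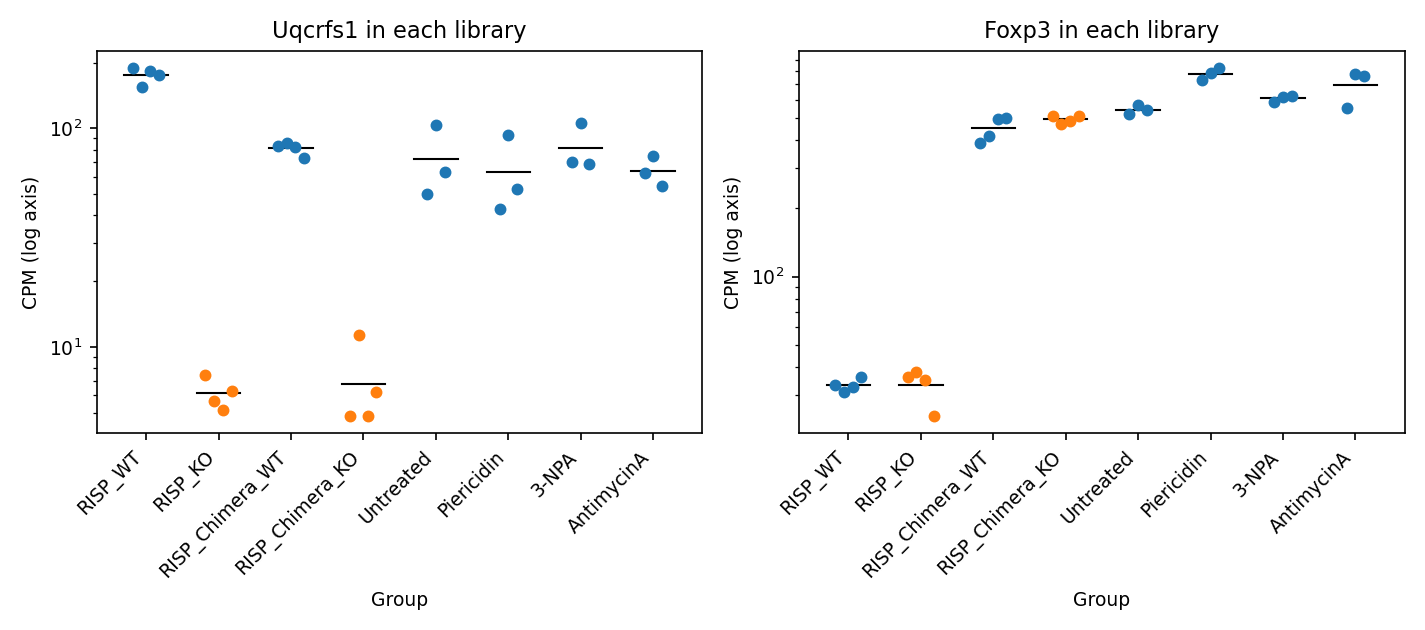
CPM of Uqcrfs1 and of Foxp3 in each of the 28 libraries by group, on a log axis. Each point is 1 library (knockouts in orange) and each bar the group mean.

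In RISP_KO Treg cells of 3-week-old mice, glycolysis was the 1 gene list called with both the preset and the estimated correlation, with 10 of its 20 measured genes higher and 0 lower. Asns, which makes asparagine, had a log2 fold change of 2.64 ± 0.28 (SE, 62.2 ± 19.9 against 9.95 ± 3.47 CPM, mean ± SD, adjusted p = 3.83e-04, n = 4 per group). Klrg1, a lectin-like receptor of terminally differentiated Treg cells, fell (-3.68 ± 0.45, 9.65 ± 7.67 against 124 ± 32.3 CPM, adjusted p = 7.01e-04). Nrp1, a semaphorin co-receptor of thymus-derived Treg cells, also fell (-1.88 ± 0.09, adjusted p = 2.67e-06), as did Pdcd1, which encodes the inhibitory receptor PD-1 (-2.00 ± 0.17, adjusted p = 9.63e-05). Il2ra, the high-affinity IL-2 receptor chain by which the cells were sorted, rose (0.59 ± 0.10, 1084 ± 80.6 against 720 ± 94.7 CPM, adjusted p = 0.00441). In total 1364 of 13832 genes were called, 661 higher and 703 lower, against 2068 called with DESeq2 and 895 with the replicate number as a block. Among the largest rises were Plac8, a small protein of activated lymphocytes (4.26 ± 0.32), Tgm2, a protein cross-linking enzyme (4.08 ± 0.42), and Ifitm2, an interferon-induced membrane protein (2.78 ± 0.30). Among the largest falls were Nrn1, a surface protein of activated T cells (-3.03 ± 0.29), Il9r, the receptor of IL-9 (-2.88 ± 0.32), and Zbtb32, a transcriptional repressor (-2.63 ± 0.21).

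Targets of ATF4, the transcription factor of the integrated stress response, rose in RISP_KO: of 28 measured, 19 rose and 0 fell (22 and 0 adjusted over the list alone). The integrated stress response list had a median log2 fold change of 0.83 (camera adjusted p = 1.89e-22, adjusted p = 0.245 with an estimated correlation). The amino acid transporter gene Slc1a4 (3.03 ± 0.22) and the alanyl-tRNA synthetase gene Aars (0.67 ± 0.07) were among them. Serine and one-carbon metabolism, which supplies nucleotide precursors, had 16 measured genes, of which 7 rose and 0 fell (11 and 0 adjusted over the list alone). The one-carbon list had a median log2 fold change of 0.39 (camera adjusted p = 3.77e-07, adjusted p = 0.362 with an estimated correlation), with Pycr1 of proline synthesis at 2.49 ± 0.28 and Shmt2 at 1.00 ± 0.13. Glycolysis had 20 genes measured, and 10 rose and 0 fell (13 and 0 adjusted over the list alone). The glycolysis list had a median log2 fold change of 0.32 (camera adjusted p = 1.28e-08, and 0.0337 with an estimated correlation). Its enzymes aldolase (Aldoa, 0.59 ± 0.07), phosphofructokinase (Pfkp, 0.61 ± 0.07) and triosephosphate isomerase (Tpi1, 0.71 ± 0.09) rose. For 20 ribosome biogenesis genes, 8 rose and 0 fell (13 and 1 adjusted over the list alone). The ribosome biogenesis list had a median log2 fold change of 0.35 (camera adjusted p = 2.14e-06, adjusted p = 0.424 with an estimated correlation), and Nop56, a component of the small nucleolar complexes that modify ribosomal RNA, had 0.63 ± 0.09. Of 25 S phase genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone). The S phase list had a median log2 fold change of 0.43 (camera adjusted p = 2.34e-07, adjusted p = 0.424 with an estimated correlation), with the replication helicase gene Mcm2 at 0.53 ± 0.10. All 25 G2 and M phase genes had positive log2 fold changes: 1 rose and 0 fell (1 and 0 adjusted over the list alone). The G2 and M list had a median log2 fold change of 0.34 (camera adjusted p = 1.25e-04, adjusted p = 0.625 with an estimated correlation). Interferon-stimulated genes numbered 26, and 9 rose and 0 fell (11 and 0 adjusted over the list alone). The interferon list had a median log2 fold change of 0.53 (camera adjusted p = 2.42e-07, adjusted p = 0.481 with an estimated correlation), led by Iigp1, a GTPase against intracellular pathogens (2.17 ± 0.29).

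Of 26 suppressive effector genes in RISP_KO, 2 rose and 7 fell (6 and 9 adjusted over the list alone). The suppressive effector list had a median log2 fold change of -0.07 (camera adjusted p = 1.27e-04, adjusted p = 0.245 with an estimated correlation), and Nt5e, which encodes the adenosine-producing enzyme CD73, fell (-1.07 ± 0.12). Treg identity genes moved in both directions: of 20, 7 rose and 3 fell (8 and 5 adjusted over the list alone). The Treg identity list had a median log2 fold change of 0.28 (camera adjusted p = 0.368), with Socs2, an IL-2 and STAT5 target, at 0.81 ± 0.11. Chemokine receptors and homing had 18 genes, of which 2 rose and 8 fell (2 and 11 adjusted over the list alone). The homing list had a median log2 fold change of -0.70 (camera adjusted p = 1.19e-04, adjusted p = 0.413 with an estimated correlation). The integrin gene Itga4 fell (-1.73 ± 0.15) and the chemokine receptor gene Ccr8 rose (1.00 ± 0.14). Among 12 mRNAs encoded in mitochondrial DNA, 0 rose and 8 fell (0 and 8 adjusted over the list alone). The mitochondrial mRNA list had a median log2 fold change of -0.55 (camera adjusted p = 5.63e-07, adjusted p = 0.331 with an estimated correlation), with mt-Nd4 of complex I at -0.81 ± 0.10 and mt-Cytb, the complex III subunit encoded there, at -0.70 ± 0.09. Monocyte and macrophage markers, 11 measured, are at low counts and fell as well: 0 rose and 4 fell (0 and 10 adjusted over the list alone). The macrophage list had a median log2 fold change of -2.24 (camera adjusted p = 1.33e-05, adjusted p = 0.362 with an estimated correlation), with Adgre1 at -3.66 ± 0.77 (0.182 ± 0.197 against 2.43 ± 1.40 CPM). In the B cell markers, 10 measured, 0 rose and 2 fell (1 and 7 adjusted over the list alone). The B cell list had a median log2 fold change of -1.04 (camera adjusted p = 6.54e-04, adjusted p = 0.362 with an estimated correlation), and Igkc had -2.18 ± 0.34. General T cell markers, 14 measured, had no positive log2 fold change: 0 rose and 4 fell (0 and 8 adjusted over the list alone). The T cell marker list had a median log2 fold change of -0.21 (camera adjusted p = 1.27e-04, adjusted p = 0.245 with an estimated correlation). With the mean of the macrophage, B cell and plasma cell markers as a covariate, a test chosen after the results were seen, 107 genes were called. Those markers differ between the genotypes, so this fit does not part the 2. Leaving out 1 library at a time gave 787 without RISP_WT replicate 1 and 788 without RISP_WT replicate 3, and at most 1486 called genes.

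In chimeras, 102 of 14399 genes tested were called in RISP_Chimera_KO, 24 higher and 78 lower. DESeq2 called 446 genes, and edgeR without a filter on low counts 208. Itgae, the integrin CD103 that holds T cells in epithelia, fell (-1.86 ± 0.27, SE, 17.2 ± 7.76 against 62.4 ± 16.9 CPM, mean ± SD, adjusted p = 0.00935, n = 4 per group). Maf, a transcription factor of effector and intestinal Treg cells, fell (-1.75 ± 0.24, 41.8 ± 18.7 against 140 ± 19.4 CPM, adjusted p = 0.00662). Serpina3g, a protease inhibitor of activated T cells, fell (-1.88 ± 0.31, adjusted p = 0.0173), as did the unconventional myosin gene Myo3b (-1.84 ± 0.20, adjusted p = 0.00119). Among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, predicted genes aside, the 2 largest rises were below 2-fold: Tmem121b, a membrane protein of little known function (0.92 ± 0.17), and the laminin-like netrin gene Ntn4 (0.88 ± 0.16).

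Suppressive effector genes in RISP_Chimera_KO, 26 measured, shifted down: 0 rose and 5 fell (0 and 15 adjusted over the list alone). This suppressive effector list had a median of -0.59 (camera adjusted p = 1.54e-21, adjusted p = 0.193 with an estimated correlation), with Nrp1 at -0.92 ± 0.12 and Nt5e at -0.75 ± 0.12. Izumo1r, the folate receptor 4 of Treg cells, fell (-0.70 ± 0.09). For the 20 Treg identity genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone). This Treg identity list had a median of 0.00 (camera adjusted p = 0.00115, adjusted p = 0.371 with an estimated correlation). Their mean was -0.16 and the test pointed down, so the median differs from both in sign. Of 16 chemokine receptor and homing genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone). This homing list had a median of -0.36 (camera adjusted p = 3.71e-07, adjusted p = 0.193 with an estimated correlation), with falls of Ccr4 (-1.72 ± 0.26), Ccr2 (-2.06 ± 0.40) and the colon-homing receptor gene Gpr15 (-1.76 ± 0.36). T cell receptor response genes Batf (-0.60 ± 0.10) and Irf4 (-0.59 ± 0.12), transcription factors of effector differentiation, fell. Mitochondrially encoded mRNAs, 13 measured, were called for mt-Cytb only (-0.94 ± 0.16): 0 rose and 1 fell (0 and 9 adjusted over the list alone). This mitochondrial mRNA list had a median of -0.62 (camera adjusted p = 3.04e-11, adjusted p = 0.352 with an estimated correlation). Integrated stress response genes, raised in RISP_KO, had 24 measured here and 0 rose and 0 fell (5 and 1 adjusted over the list alone). This integrated stress response list had a median of 0.21 (camera adjusted p = 0.00466, adjusted p = 0.352 with an estimated correlation). Slc1a4 (1.62 ± 0.40, adjusted p = 0.101) and Gpt2 (1.26 ± 0.33, adjusted p = 0.116) had the smallest p and were not called. G2 and M phase genes moved up as a list of 25: 1 rose and 0 fell (22 and 0 adjusted over the list alone). This G2 and M list had a median of 1.04 (camera adjusted p = 1.65e-22, adjusted p = 0.247 with an estimated correlation), with the mitotic motor gene Cenpe at 1.02 ± 0.20. Monocyte and macrophage markers, 12 measured, had 11 positive log2 fold changes: 0 rose and 0 fell (0 and 0 adjusted over the list alone). This macrophage list had a median of 0.60 (camera adjusted p = 0.0102, adjusted p = 0.554 with an estimated correlation). The macrophage list was not called without RISP_Chimera_WT replicates 2 or 3 and RISP_Chimera_KO replicates 2 or 4 (adjusted p = 0.0530 to 0.201). Dendritic cell markers, 8 measured, had 7 positive ones: 0 rose and 0 fell (0 and 0 adjusted over the list alone). This dendritic cell list had a median of 0.92 (camera adjusted p = 0.00650, adjusted p = 0.530 with an estimated correlation), and it was not called without RISP_Chimera_KO replicate 2 (adjusted p = 0.0946). General T cell markers numbered 14, and 0 rose and 0 fell (0 and 1 adjusted over the list alone). This T cell marker list had a median of -0.10 (camera adjusted p = 0.0102, adjusted p = 0.530 with an estimated correlation), and it was not called without RISP_Chimera_WT replicate 2 (adjusted p = 0.0625). For 4 natural killer cell markers, 0 rose and 0 fell (1 and 0 adjusted over the list alone). This natural killer cell list had a median of 0.64 (camera adjusted p = 0.0367, adjusted p = 0.371 with an estimated correlation), and it was not called without RISP_Chimera_WT replicate 3 and RISP_Chimera_KO replicate 4 (adjusted p = 0.0778 to 0.164). For 3 epithelial or pancreatic markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone). This epithelial or pancreatic list had a median of -1.21 (camera adjusted p = 0.00614, adjusted p = 0.247 with an estimated correlation). The mean log2 CPM of B cell, plasma cell and macrophage markers, centred in this table, was 0.80 and 1.06 in RISP_Chimera_KO replicates 2 and 4, against -0.56 to 0.00 in the other 6 libraries. With that mean as a covariate 183 genes were called, and without those 2 libraries 247, both chosen after the results were seen. Leaving out 1 library changed the count to 49 without RISP_Chimera_WT replicate 1, 33 without RISP_Chimera_WT replicate 2, 53 without RISP_Chimera_WT replicate 3, 46 without RISP_Chimera_WT replicate 4, 58 without RISP_Chimera_KO replicate 1, 177 without RISP_Chimera_KO replicate 2 and 38 without RISP_Chimera_KO replicate 3. Of 19 genes called and named for the chimeras here, 7 (Uqcrfs1, Itgae, Maf, Myo3b, Nrp1, Izumo1r and Ccr4) kept their call without each library in turn, and 12 lost it without 1 or more, at adjusted p up to 0.136. The lost calls numbered 6 without RISP_Chimera_KO replicate 1, 1 without RISP_Chimera_KO replicate 2, 9 without RISP_Chimera_KO replicate 3, 4 without RISP_Chimera_KO replicate 4, 10 without RISP_Chimera_WT replicate 1, 12 without RISP_Chimera_WT replicate 2, 8 without RISP_Chimera_WT replicate 3 and 10 without RISP_Chimera_WT replicate 4.

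The knockout effect itself was compared between chimeras and 3-week-old mice in 1 fit of the 4 groups (n = 4 each), and 509 of 15580 genes differed, 191 with a more positive and 318 with a more negative knockout effect in chimeras. Klrg1 had a less negative effect in chimeras (difference in log2 fold change 2.96 ± 0.55, SE, adjusted p = 0.00483), and so did Nrn1 (2.73 ± 0.40, adjusted p = 7.57e-04) and Nrp1 (0.95 ± 0.16, adjusted p = 0.00319). Itgae had a more negative effect in chimeras (-2.52 ± 0.40, adjusted p = 0.00175), as did Tgm2 (-4.01 ± 0.54, adjusted p = 3.97e-04) and Csf1, a macrophage growth factor (-2.33 ± 0.37, adjusted p = 0.00146). Asns differed by -2.11 ± 0.47 (adjusted p = 0.0169, not called without RISP_Chimera_WT replicates 3 or 4, adjusted p = 0.0539 to 0.0629), and Stc2, a secreted stress protein under ATF4 control, by -4.58 ± 0.69 (adjusted p = 0.00109). Over the 28 integrated stress response genes, 0 had a more positive and 6 a more negative effect in chimeras (0 and 13 adjusted over the list alone). The median integrated stress response difference was -0.67 (camera adjusted p = 7.89e-09, adjusted p = 0.231 with an estimated correlation). Over 20 glycolysis genes, 0 had a more positive and 7 a more negative effect in chimeras (0 and 9 adjusted over the list alone). The median glycolysis difference was -0.31 (camera adjusted p = 2.88e-07, adjusted p = 0.231 with an estimated correlation). Over 25 G2 and M phase genes, 1 had a more positive and 0 a more negative effect in chimeras (1 and 0 adjusted over the list alone). The median G2 and M difference was 0.68 (camera adjusted p = 3.77e-08, adjusted p = 0.398 with an estimated correlation). Over 26 interferon-stimulated genes, 0 had a more positive and 6 a more negative effect in chimeras (0 and 7 adjusted over the list alone). The median interferon difference was -0.43 (camera adjusted p = 4.27e-06, adjusted p = 0.450 with an estimated correlation). Markers of other cell types differed too. Over 12 monocyte and macrophage markers, 5 had a more positive and 0 a more negative effect in chimeras (9 and 0 adjusted over the list alone). The median macrophage difference was 2.86 (camera adjusted p = 5.29e-09, adjusted p = 0.231 with an estimated correlation). Over 9 dendritic cell markers, 1 had a more positive and 0 a more negative effect in chimeras (3 and 0 adjusted over the list alone). The median dendritic cell difference was 1.55 (camera adjusted p = 0.00226, adjusted p = 0.316 with an estimated correlation). Over 13 B cell markers, 0 had a more positive and 0 a more negative effect in chimeras (3 and 1 adjusted over the list alone). The median B cell difference was 1.19 (camera adjusted p = 0.00635, adjusted p = 0.450 with an estimated correlation). These are 7 of the 22 lists called for the difference with the preset correlation, of 47 tested, and 0 were called with the estimated one. Age, kit and the making of chimeras differ together between these tables, as do the levels of sex-linked transcripts, and cannot be told apart. For Uqcrfs1 the difference was 1.20 ± 0.27 (adjusted p = 0.0191), with a lower level in RISP_Chimera_WT than in RISP_WT. The count was 323 without RISP_WT replicate 3, 854 with DESeq2 and 324 with the replicate number as a block.

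Across 12850 genes tested in both, the log2 fold changes of the 2 knockouts had a Pearson r of 0.14, and of 0.274 among the 8223 with a mean log2 CPM of at least 3. Called genes shared 35 falls, against 4.09 by chance (n1 × n2/N), and 4 rises against 1.11. The shared falls, picked for naming after the values were seen, include Uqcrfs1, Nrp1, Nt5e, Maf, the secreted suppressor gene Fgl2 (-1.85 in RISP_KO and -1.91 in RISP_Chimera_KO), Ccr4, Gpr15 and mt-Cytb. Satb1, a chromatin organizer of resting T cells, rose in both (1.15 and 0.42). Rising in RISP_KO and falling in RISP_Chimera_KO were Csf1, Socs2, Irf4, Batf, the cytokine signalling inhibitor gene Socs3 and the cystatin gene Cst7, also named after the values were seen (6 genes, 3.76 by chance). The reverse held for 2 genes (1.21 by chance).

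With piericidin, the lists of G2 and M phase, S phase and ribosome biogenesis genes were called lower and that of HIF targets higher. Gpt2, the mitochondrial alanine aminotransferase under ATF4 control, rose by a log2 fold change of 2.19 ± 0.40 (SE, 25.2 ± 2.52 against 5.45 ± 3.00 CPM, mean ± SD, adjusted p = 1.62e-04, n = 3 per group), and Asns by 1.29 ± 0.22 (adjusted p = 5.31e-05). Bnip3, a mitophagy receptor and HIF target, rose (1.61 ± 0.40, adjusted p = 0.00427), as did Tnfrsf9, the co-stimulatory receptor 4-1BB (1.03 ± 0.09, 1685 ± 157 against 824 ± 70.6 CPM, adjusted p = 2.19e-10), and Foxp3 (0.51 ± 0.09, 784 ± 40.6 against 552 ± 21.4 CPM, adjusted p = 1.69e-04). The replication factor gene Mcm10 fell (-2.30 ± 0.23, adjusted p = 8.38e-09), with the mitotic kinase gene Cdk1 (-2.10 ± 0.27) and cyclin B1 (Ccnb1, -2.26 ± 0.35). In all, 1584 of 11689 genes were called, 657 higher and 927 lower. Of 25 G2 and M phase genes, 0 rose and 25 fell (0 and 25 adjusted over the list alone). For the G2 and M list the median was -1.46 (camera adjusted p = 3.71e-39, and 0.0243 with an estimated correlation). In S phase, 25 genes were measured and 0 rose and 23 fell (0 and 25 adjusted over the list alone). For the S phase list the median was -0.88 (camera adjusted p = 1.89e-36, and 0.0243 with an estimated correlation), with Rrm2 of deoxynucleotide synthesis at -1.89 ± 0.18. Ribosome biogenesis genes fell (20 measured): 0 rose and 17 fell (0 and 18 adjusted over the list alone). For the ribosome biogenesis list the median was -0.58 (camera adjusted p = 2.32e-20, and 0.00433 with an estimated correlation), with the nucleolar proteins Ncl (-0.59 ± 0.08) and Nolc1 (-0.71 ± 0.10). Nucleotide synthesis, 17 genes, had the same sign: 0 rose and 13 fell (0 and 13 adjusted over the list alone). For the nucleotide synthesis list the median was -0.52 (camera adjusted p = 6.63e-13, and 0.0243 with an estimated correlation). Of 14 HIF targets, 4 rose and 0 fell (7 and 0 adjusted over the list alone). For the HIF list the median was 0.47 (camera adjusted p = 2.90e-04, and 0.0243 with an estimated correlation), with Pdk1, which restrains pyruvate oxidation, at 0.66 ± 0.14. Histone demethylases that use 2-oxoglutarate numbered 14, and 6 rose and 0 fell (9 and 0 adjusted over the list alone). For the demethylase list the median was 0.34 (camera adjusted p = 5.20e-05, and 0.0243 with an estimated correlation), with Kdm5b at 0.67 ± 0.13. Endoplasmic reticulum stress response genes (16 genes) went down: 0 rose and 7 fell (0 and 10 adjusted over the list alone). For the endoplasmic reticulum stress list the median was -0.24 (camera adjusted p = 0.00123, and 0.0243 with an estimated correlation). Of 36 mitochondrial ribosomal protein genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone). For the mitochondrial ribosomal protein list the median was -0.26 (camera adjusted p = 3.02e-04, and 0.0243 with an estimated correlation). For 24 integrated stress response genes, 8 rose and 1 fell (10 and 2 adjusted over the list alone). For the integrated stress response list the median was 0.38 (camera adjusted p = 0.00120, adjusted p = 0.136 with an estimated correlation). Among 26 suppressive effectors, 6 rose and 1 fell (7 and 1 adjusted over the list alone). For the suppressive effector list the median was 0.11 (camera adjusted p = 0.00138, adjusted p = 0.110 with an estimated correlation), with granzyme B (Gzmb, 1.09 ± 0.21) and the TGF-β activating integrin gene Itgb8 (0.91 ± 0.14) rising. Of 5 B cell markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone). For the B cell list the median was -0.76 (camera adjusted p = 0.0433, adjusted p = 0.264 with an estimated correlation), and it was not called without Untreated replicates 1 or 2 and Piericidin replicates 1 or 2 (adjusted p = 0.0533 to 0.102). Of 4 sex-linked genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone). For the sex-linked list the median was 0.40 (camera adjusted p = 0.0135, adjusted p = 0.110 with an estimated correlation). The number called was 1027 without Untreated replicate 1 and 1009 without Piericidin replicate 3.

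With 3-NPA, the list of mitochondrial mRNAs was called lower and that of p53 targets higher. The small ribosomal RNA mt-Rnr1 rose by a log2 fold change of 2.20 ± 0.11 (SE, 3554 ± 518 against 773 ± 121 CPM, mean ± SD, adjusted p = 2.48e-18, n = 3 per group), and mt-Cytb fell (-2.59 ± 0.12, 446 ± 73.3 against 2690 ± 249 CPM, adjusted p = 7.45e-19). mt-Nd4 (-2.19 ± 0.15) and mt-Nd5 (-1.92 ± 0.11), subunits of complex I, fell as well. Cdkn1a, the p53-induced inhibitor of cell cycle kinases, rose (1.60 ± 0.19, 90.1 ± 7.01 against 29.7 ± 8.62 CPM, adjusted p = 3.81e-07), as did Psrc1, a spindle protein under p53 control (1.66 ± 0.34, adjusted p = 0.00351, not called without Untreated replicate 1, adjusted p = 0.0507). Il10 fell (-0.81 ± 0.24, 20.1 ± 6.93 against 35.6 ± 5.06 CPM, adjusted p = 0.0490, not called without Untreated replicates 1, 2 or 3 and 3-NPA replicates 1 or 2, adjusted p = 0.0821 to 0.240), and Foxp3 was not called (0.13 ± 0.09, adjusted p = 0.537). This inhibitor gave 377 called genes of 11689, 158 higher and 219 lower. Among 7 mitochondrial mRNAs, 0 rose and 7 fell (0 and 7 adjusted over the list alone). Over the mitochondrial mRNA list the median was -1.92 (camera adjusted p = 5.08e-85, and 0.00143 with an estimated correlation). Of 14 p53 targets, 4 rose and 0 fell (8 and 0 adjusted over the list alone). Over the p53 list the median was 0.46 (camera adjusted p = 7.79e-12, and 0.0151 with an estimated correlation), with Ccng1, a cyclin G, at 0.48 ± 0.10. Of 20 ribosome biogenesis genes, 0 rose and 5 fell (0 and 11 adjusted over the list alone). Over the ribosome biogenesis list the median was -0.31 (camera adjusted p = 3.64e-10, and 0.0151 with an estimated correlation), and Ncl was at -0.43 ± 0.08. Among 25 S phase genes, 0 rose and 10 fell (0 and 19 adjusted over the list alone). Over the S phase list the median was -0.54 (camera adjusted p = 1.01e-17, adjusted p = 0.166 with an estimated correlation). Among 25 G2 and M phase genes, 0 rose and 6 fell (0 and 11 adjusted over the list alone). Over the G2 and M list the median was -0.61 (camera adjusted p = 2.75e-11, adjusted p = 0.182 with an estimated correlation). Integrated stress response genes (24) included falls of Atf4 itself (-0.39 ± 0.10, not called without Untreated replicates 1 or 3 and 3-NPA replicates 1 or 3, adjusted p = 0.0887 to 0.175) and of the amino acid transporter gene Slc7a5 (-0.64 ± 0.12): 0 rose and 3 fell (2 and 5 adjusted over the list alone). Over the integrated stress response list the median was -0.11 (camera adjusted p = 0.0888), and without 3-NPA replicate 1 the list was called lower (adjusted p = 0.0304). General T cell markers had 14 measured, and 0 rose and 2 fell (1 and 6 adjusted over the list alone). Over the T cell marker list the median was -0.14 (camera adjusted p = 0.0131, adjusted p = 0.180 with an estimated correlation), and it was not called without Untreated replicate 3 and 3-NPA replicates 1 or 3 (adjusted p = 0.0516 to 0.0639). Among 4 sex-linked genes, 0 rose and 0 fell (1 and 0 adjusted over the list alone). Over the sex-linked list the median was 0.22 (camera adjusted p = 0.0495, adjusted p = 0.180 with an estimated correlation), and it was not called without Untreated replicates 1 or 3 and 3-NPA replicates 1 or 3 (adjusted p = 0.0543 to 0.172). Leaving out 1 library gave 153 without Untreated replicate 1, 172 without Untreated replicate 3, 180 without 3-NPA replicate 2 and 130 without 3-NPA replicate 3.

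With antimycin A, the lists of mitochondrial mRNAs and of S phase and G2 and M phase genes were called lower and that of p53 targets higher. mt-Rnr1 rose (2.19 ± 0.11, SE, adjusted p = 1.89e-18, n = 3 per group) and mt-Cytb fell (-2.87 ± 0.12, 368 ± 95.2 against 2690 ± 249 CPM, mean ± SD, adjusted p = 3.35e-20). The mitotic kinase gene Pbk fell (-3.02 ± 0.42, adjusted p = 9.55e-07), with Ube2c, which directs mitotic proteins to destruction (-2.75 ± 0.32), and Ccnb1 (-2.75 ± 0.37). Cdkn1a (1.63 ± 0.19, 91.7 ± 18.2 against 29.7 ± 8.62 CPM, adjusted p = 3.66e-08) and Ccng1 (1.05 ± 0.10, adjusted p = 2.78e-10) rose. Foxp3 rose (0.34 ± 0.09, 698 ± 130 against 552 ± 21.4 CPM, adjusted p = 0.00930, not called without Untreated replicate 1 and AntimycinA replicates 2 or 3, adjusted p = 0.0519 to 0.128) and Il2ra fell (-0.32 ± 0.07, 2337 ± 84.5 against 2924 ± 75.1 CPM, adjusted p = 0.00102). Antimycin A changed 1754 of 11689 genes, 760 higher and 994 lower. Of 25 G2 and M phase genes, 0 rose and 25 fell (0 and 25 adjusted over the list alone). The G2 and M list median was -2.04 (camera adjusted p = 9.04e-52, and 0.0132 with an estimated correlation). Of 25 S phase genes, 0 rose and 25 fell (0 and 25 adjusted over the list alone). The S phase list median was -1.29 (camera adjusted p = 2.01e-52, and 0.0117 with an estimated correlation). Ribosome biogenesis had 20 genes, and 0 rose and 19 fell (0 and 20 adjusted over the list alone). The ribosome biogenesis list median was -0.51 (camera adjusted p = 1.63e-18, and 0.00298 with an estimated correlation). Of 17 nucleotide synthesis genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone). The nucleotide synthesis list median was -0.52 (camera adjusted p = 1.64e-10, and 0.0236 with an estimated correlation). Of 36 mitochondrial ribosomal protein genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone). The mitochondrial ribosomal protein list median was -0.28 (camera adjusted p = 0.00206, and 0.0382 with an estimated correlation). Mitochondrial mRNAs numbered 7, and 0 rose and 7 fell (0 and 7 adjusted over the list alone). The mitochondrial mRNA list median was -1.95 (camera adjusted p = 9.67e-58, and 0.00298 with an estimated correlation). Of 14 p53 targets, 11 rose and 0 fell (12 and 0 adjusted over the list alone). The p53 list median was 0.73 (camera adjusted p = 3.33e-13, and 0.0117 with an estimated correlation). Glycolysis genes, 20 measured, went down: 0 rose and 9 fell (1 and 9 adjusted over the list alone). The glycolysis list median was -0.30 (camera adjusted p = 2.43e-05, adjusted p = 0.141 with an estimated correlation), with lactate dehydrogenase (Ldha) at -0.84 ± 0.09 and Gapdh at -0.77 ± 0.09. Integrated stress response genes, 24 measured, were mixed: 7 rose and 2 fell (8 and 4 adjusted over the list alone). The integrated stress response list median was 0.30 (camera adjusted p = 0.0191, adjusted p = 0.212 with an estimated correlation), with the stress sensor gene Sesn2 at 1.56 ± 0.26 and Asns at 0.99 ± 0.22. Of 26 suppressive effectors, 9 rose and 0 fell (10 and 0 adjusted over the list alone). The suppressive effector list median was 0.18 (camera adjusted p = 2.58e-04, adjusted p = 0.0622 with an estimated correlation), with Pdcd1 at 0.86 ± 0.16, the inhibitory receptor gene Tigit at 0.62 ± 0.12 and Tnfrsf9 at 0.76 ± 0.09. Cytosolic heat shock genes (7 measured) fell: 0 rose and 4 fell (0 and 6 adjusted over the list alone). The heat shock list median was -0.53 (camera adjusted p = 5.09e-08, and 0.0461 with an estimated correlation), with the constitutive chaperone gene Hspa8 at -0.86 ± 0.08. Of 16 endoplasmic reticulum stress response genes, 0 rose and 9 fell (0 and 11 adjusted over the list alone). The endoplasmic reticulum stress list median was -0.33 (camera adjusted p = 3.35e-04, and 0.0191 with an estimated correlation). Of 14 histone demethylases that use 2-oxoglutarate, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The demethylase list median was 0.25 (camera adjusted p = 6.16e-04, and 0.0461 with an estimated correlation). Igkc, an antibody light chain of B cells, rose from near 0 counts (4.02 ± 1.04, 7.36 ± 5.79 against 0.392 ± 0.679 CPM, adjusted p = 0.00404, not called without AntimycinA replicate 2, adjusted p = 0.0984).

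**Figure D2:**
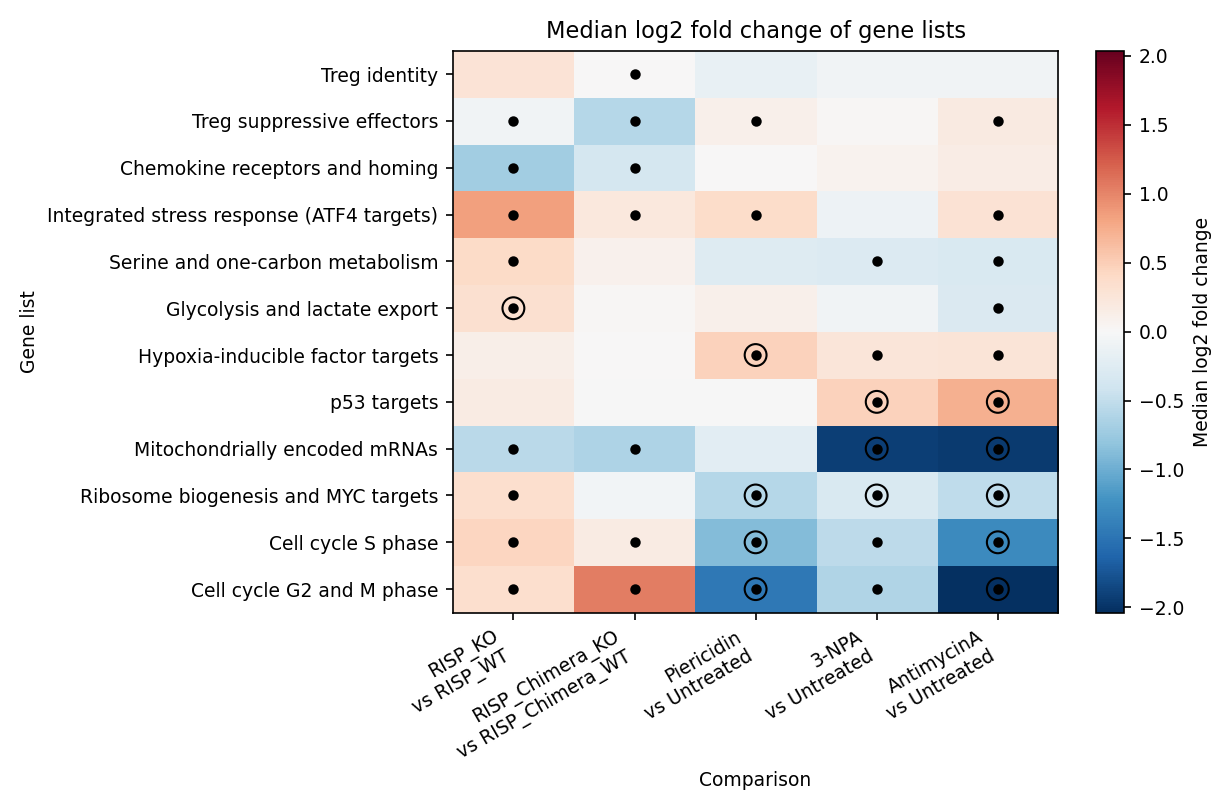
Median log2 fold change of the measured genes of 12 gene lists in the 2 knockouts and the 3 inhibitors. A dot marks camera adjusted p under 0.05 with the preset correlation, a ring the same with the estimated correlation.

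RNAs of mitochondrial DNA changed by their place on the heavy-strand transcript, an analysis chosen after the results were seen. From the ribosomal RNAs at its start to mt-Cytb at its end, the rank correlation of position and log2 fold change was -0.95 for 3-NPA and -0.95 for antimycin A (exact permutation p = 0.00114 each, n = 8 genes), and -0.24 for piericidin (exact permutation p = 0.582, n = 8 genes). In the knockouts it was -0.85 over 13 genes for RISP_KO (permutation test, adjusted p = 0.00179) and -0.85 over 14 genes for RISP_Chimera_KO (permutation test, adjusted p = 0.00162). These p-values treat the genes as independent and do not measure the spread between libraries. For piericidin, mt-Co1, the catalytic subunit of complex IV, rose (0.51 ± 0.10), while mt-Nd2 (-0.51 ± 0.11) and mt-Cytb (-0.44 ± 0.11, not called without Untreated replicate 1 and Piericidin replicate 2, adjusted p = 0.0705 to 0.0882) fell. mt-Nd6, the single mRNA of the light strand, fell with 3-NPA (-2.02 ± 0.14) and with antimycin A (-1.95 ± 0.14). It spans bases 13552 to 14070 and overlaps mt-Nd5, on the other strand, only up to base 13565. The labels do not state the strand used for counting.

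**Figure D3:**
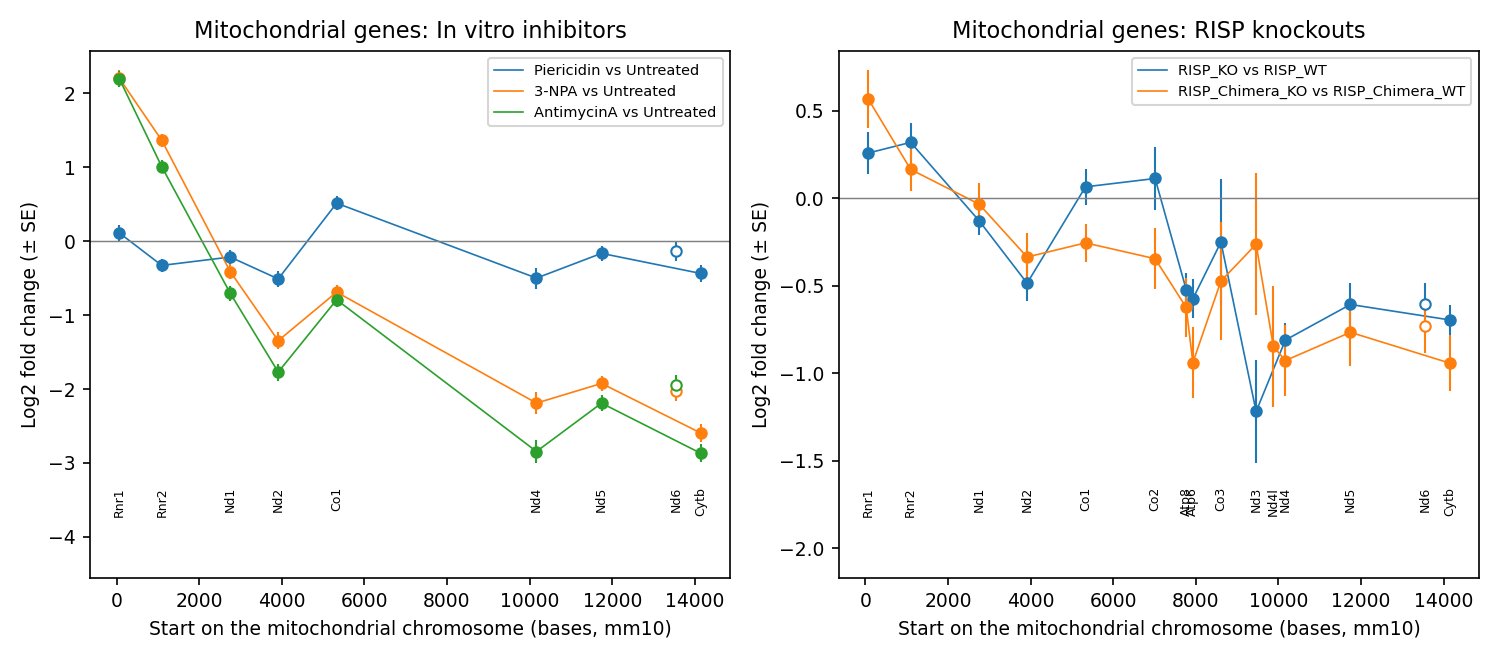
Log2 fold change (± SE) of mitochondrially encoded genes by start position on the mitochondrial chromosome, for the 3 inhibitors and the 2 knockouts. The light-strand gene mt-Nd6 is drawn as an open symbol.

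Antimycin A and piericidin differed at 86 of 11689 genes (51 higher and 35 lower with antimycin A, n = 3 per group). RNAs of mitochondrial DNA and p53 targets were among them. Cdkn1a was higher with antimycin A (2.36 ± 0.20, SE, adjusted p = 4.94e-11), as were Phlda3, a p53-induced inhibitor of AKT (2.15 ± 0.26), and mt-Rnr1 (2.08 ± 0.11), while mt-Cytb (-2.43 ± 0.12) and mt-Nd4 (-2.35 ± 0.16) were lower. Of 14 p53 targets, 8 were higher and 0 lower (10 and 0 adjusted over the list alone). The p53 median was 0.58 (camera adjusted p = 1.72e-35, and 5.11e-04 with an estimated correlation). Of 7 mitochondrial mRNAs, 0 were higher and 7 lower (0 and 7 adjusted over the list alone). The mitochondrial mRNA median was -1.81 (camera adjusted p = 3.18e-127, and 2.95e-04 with an estimated correlation). Glycolysis, 20 genes, was lower: 0 were higher and 8 lower (0 and 11 adjusted over the list alone). The glycolysis median was -0.36 (camera adjusted p = 3.28e-15, adjusted p = 0.0721 with an estimated correlation), with Tpi1 at -1.10 ± 0.12. For 25 G2 and M phase genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone). The G2 and M median was -0.52 (camera adjusted p = 1.77e-07, adjusted p = 0.374 with an estimated correlation), and without AntimycinA replicate 3 the list was not called (adjusted p = 0.284). Markers of other cells and of T cells differed too. For 5 B cell markers, 1 was higher and 0 lower (3 and 0 adjusted over the list alone). The B cell median was 0.89 (camera adjusted p = 0.00652, adjusted p = 0.238 with an estimated correlation), and it was not called without AntimycinA replicate 2 (adjusted p = 0.0674). For 3 dendritic cell markers, 1 was higher and 0 lower (2 and 0 adjusted over the list alone). The dendritic cell median was 0.83 (camera adjusted p = 0.0208, adjusted p = 0.232 with an estimated correlation), and it was not called without Piericidin replicates 1 or 3 (adjusted p = 0.0609 to 0.0902). For 14 general T cell markers, 0 were higher and 0 lower (5 and 0 adjusted over the list alone). The T cell marker median was 0.15 (camera adjusted p = 0.0115, adjusted p = 0.238 with an estimated correlation), and it was not called without Piericidin replicate 3 and AntimycinA replicate 3 (adjusted p = 0.0571 to 0.0749). Leaving out 1 library gave 43 without Piericidin replicate 1, 57 without AntimycinA replicate 1 and 55 without AntimycinA replicate 2.

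Antimycin A against 3-NPA left 465 called genes (187 higher and 278 lower with antimycin A, n = 3 per group). The lists of G2 and M phase, S phase and ribosome biogenesis genes were called lower. Pbk (-2.37 ± 0.43, SE, adjusted p = 4.46e-04), Ccnb1 (-2.13 ± 0.37) and the polo-like kinase gene Plk1 (-1.95 ± 0.33) were lower with antimycin A. Higher were Pam, an enzyme that amidates peptides (1.53 ± 0.38, not called without 3-NPA replicate 1 and AntimycinA replicate 3, adjusted p = 0.0960 to 0.107), the protease cathepsin E (Ctse, 1.47 ± 0.35, not called without AntimycinA replicates 1 or 2, adjusted p = 0.0521 to 0.0528) and Arrdc3, an arrestin-like regulator of receptors (1.39 ± 0.27). For 25 G2 and M phase genes, 0 were higher and 21 lower (0 and 24 adjusted over the list alone). That G2 and M list had a median of -1.37 (camera adjusted p = 5.44e-50, and 0.0340 with an estimated correlation). For 25 S phase genes, 0 were higher and 20 lower (0 and 23 adjusted over the list alone). That S phase list had a median of -0.75 (camera adjusted p = 1.07e-37, and 0.0340 with an estimated correlation). For 20 ribosome biogenesis genes, 0 were higher and 5 lower (0 and 12 adjusted over the list alone). That ribosome biogenesis list had a median of -0.28 (camera adjusted p = 1.19e-08, and 0.0340 with an estimated correlation). For 24 integrated stress response genes, 7 were higher and 0 lower (14 and 0 adjusted over the list alone). That integrated stress response list had a median of 0.41 (camera adjusted p = 2.43e-07, and 0.0451 with an estimated correlation), with Atf4 (0.43 ± 0.10, not called without 3-NPA replicates 1 or 3 and AntimycinA replicate 3, adjusted p = 0.0606 to 0.136) and Ddit3, which encodes CHOP (1.15 ± 0.28, not called without 3-NPA replicate 1, adjusted p = 0.0887). Of 26 suppressive effectors, 3 were higher and 0 lower (8 and 0 adjusted over the list alone). That suppressive effector list had a median of 0.21 (camera adjusted p = 6.31e-06, and 0.0451 with an estimated correlation), with Tnfrsf9 at 0.52 ± 0.09 and Itgae at 0.74 ± 0.13. Of 7 mitochondrial mRNAs, 0 were higher and 2 lower (0 and 5 adjusted over the list alone). That mitochondrial mRNA list had a median of -0.27 (camera adjusted p = 8.57e-04, adjusted p = 0.351 with an estimated correlation), and without AntimycinA replicate 1 the list was not called (adjusted p = 0.167). General T cell markers, 14 measured, were higher too: 7 were higher and 0 lower (8 and 0 adjusted over the list alone). That T cell marker list had a median of 0.24 (camera adjusted p = 1.04e-07, and 0.0340 with an estimated correlation). Leaving out 1 library gave 188 without 3-NPA replicate 1, 279 without 3-NPA replicate 3, 308 without AntimycinA replicate 2 and 194 without AntimycinA replicate 3.

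Piericidin against 3-NPA gave 502 called genes (218 higher and 284 lower with piericidin, n = 3 per group). mt-Cytb (2.16 ± 0.12, SE, adjusted p = 1.04e-16) and Arrdc3 (1.97 ± 0.27) were higher with piericidin, and Cdkn1a (-2.33 ± 0.20), mt-Rnr1 (-2.09 ± 0.11) and Lif, a cytokine of the IL-6 family (-1.86 ± 0.21), were lower. Foxp3 (0.38 ± 0.09, adjusted p = 0.0130, not called without Piericidin replicate 3 and 3-NPA replicate 1, adjusted p = 0.0792 to 0.0839) and Il10 (0.94 ± 0.24, adjusted p = 0.0170, not called without Piericidin replicate 3 and 3-NPA replicate 1, adjusted p = 0.146 to 0.148) were higher with piericidin. Integrated stress response genes, 24 measured, parted the 2 inhibitors: 9 were higher and 0 lower (11 and 0 adjusted over the list alone). Here the integrated stress response list had a median of 0.42 (camera adjusted p = 2.46e-09, and 0.0405 with an estimated correlation), with Asns at 1.13 ± 0.22 and Slc1a4 at 2.69 ± 0.52. Of 7 mitochondrial mRNAs, 6 were higher and 0 lower (6 and 0 adjusted over the list alone). Here the mitochondrial mRNA list had a median of 1.69 (camera adjusted p = 8.67e-62, and 0.00459 with an estimated correlation). Of 25 G2 and M phase genes, 0 were higher and 11 lower (0 and 24 adjusted over the list alone). Here the G2 and M list had a median of -0.96 (camera adjusted p = 9.66e-23, adjusted p = 0.0976 with an estimated correlation). Of 25 S phase genes, 0 were higher and 8 lower (0 and 17 adjusted over the list alone). Here the S phase list had a median of -0.41 (camera adjusted p = 1.48e-12, adjusted p = 0.185 with an estimated correlation). Of 14 p53 targets, 0 were higher and 5 lower (0 and 10 adjusted over the list alone). Here the p53 list had a median of -0.59 (camera adjusted p = 3.31e-12, and 0.0188 with an estimated correlation). Of 20 ribosome biogenesis genes, 0 were higher and 5 lower (1 and 9 adjusted over the list alone). Here the ribosome biogenesis list had a median of -0.27 (camera adjusted p = 3.17e-07, and 0.0405 with an estimated correlation). Of 14 general T cell markers, 1 was higher and 0 lower (1 and 0 adjusted over the list alone). Here the T cell marker list had a median of 0.17 (camera adjusted p = 0.00893, adjusted p = 0.185 with an estimated correlation). Leaving out 1 library gave 302 without Piericidin replicate 2, 231 without Piericidin replicate 3, 230 without 3-NPA replicate 1 and 287 without 3-NPA replicate 3.

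The inhibitors share the untreated libraries, which alone gives a correlation: in 20 simulated draws with no effect of any inhibitor, r was 0.488 for piericidin and antimycin A, 0.493 for piericidin and 3-NPA and 0.496 for 3-NPA and antimycin A. The measured r were 0.71, 0.53 and 0.60, and the covariances 0.206, 0.124 and 0.153 against 0.0470, 0.0476 and 0.0476 in the draws. Piericidin and antimycin A shared 379 rises (42.7 by chance, n1 × n2/N) and 655 falls (78.8), piericidin and 3-NPA 92 rises (8.88) and 155 falls (17.4), and 3-NPA and antimycin A 109 rises (10.3) and 176 falls (18.6). In the draws the mean number of shared rises was 0.05, 0.05 and 0, and that of shared falls 0 each. The draws hold no effect of any inhibitor, so few calls of any kind are expected in them. These numbers therefore do not show how far the shared libraries raise the overlap of called genes. Only 3 untreated libraries exist and cannot be divided between inhibitors, so part of each excess of shared calls over n1 × n2/N may come from them. The measured covariances lie 0.159, 0.0769 and 0.105 above those of the draws. With all 3 inhibitors, 75 genes rose and 148 fell.

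Over all genes tested in both, RISP_KO had a Pearson r of -0.11 with piericidin, -0.09 with 3-NPA and -0.13 with antimycin A (11023 genes), and RISP_Chimera_KO 0.00, -0.03 and -0.10 (11205 genes). Among genes with a mean log2 CPM of at least 3 these were -0.197, -0.124 and -0.198 for RISP_KO and 0.111, 0.0555 and 0.0185 for RISP_Chimera_KO, and by Spearman over all genes -0.168, -0.116 and -0.175, and 0.0959, 0.0254 and 0.00614. The sign of RISP_Chimera_KO with 3-NPA and with antimycin A thus depends on the genes and the measure. Of genes called in both RISP_KO and antimycin A, 146 (51.1 by chance) rose in RISP_KO and fell with the inhibitor, 74 (39.7) fell and rose, 57 (39.2) rose in both and 21 (51.8) fell in both. For piericidin these 4 numbers were 149 (47.8 by chance), 54 (34.1), 29 (33.6) and 24 (48.4), and for 3-NPA 41 (11.2 by chance), 19 (8.24), 12 (8.12) and 14 (11.4). Mcm2, Nop56, Tpi1 and Cad, the first enzyme of pyrimidine synthesis (0.70 in RISP_KO), are examples with antimycin A (-1.08, -0.39, -0.85 and -0.54), named after the values were seen. The RISP_KO and in vitro comparisons also differ in kit, culture, depth and the levels of sex-linked transcripts. How far these shape the shared or opposite signs was not tested.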

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

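The tests of mitochondrial RNAs, of G2 and M phase genes and of the Foxp3 level in this part were chosen after the results were seen, while the test of the difference between knockout effects was planned.

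The knockout effect differed between chimeras and 3-week-old mice for 509 genes, by a test of the difference itself in 1 fit of the 4 groups. Among genes named in the report, the effect in chimeras was more negative for Plac8 (-4.82), Stc2 (-4.58), Tgm2 (-4.01), Ifitm2 (-3.36), Itgae (-2.52), Csf1 (-2.33), Iigp1 (-2.30), Asns (-2.11), Serpina3g (-2.07), Ccr8 (-1.53), Socs2 (-1.34), Batf (-1.33), Irf4 (-1.20), Myo3b (-1.15), Izumo1r (-0.94), Nop56 (-0.85), Shmt2 (-0.72), Tpi1 (-0.66), Pfkp (-0.61), Mcm2 (-0.51) and Aldoa (-0.45). It was more positive for Adgre1 (3.94), Klrg1 (2.96), Nrn1 (2.73), Zbtb32 (2.31), Ntn4 (1.89), Tmem121b (1.58), Itga4 (1.51), Pdcd1 (1.44), Uqcrfs1 (1.20) and Nrp1 (0.95). Of 47 lists, 22 were called for this difference with the preset correlation and 0 with the estimated one. The medians of the 7 given in the report were -0.67 for integrated stress response genes, -0.31 for glycolysis genes, 0.68 for G2 and M phase genes, -0.43 for interferon-stimulated genes, 2.86 for monocyte and macrophage markers, 1.55 for dendritic cell markers and 1.19 for B cell markers. Age, library kit, the making of chimeras and the levels of sex-linked transcripts are confounded with the table, and none of them was tested. Within the 3-week-old mice these transcripts also differ by replicate number, alike in both genotypes, and the labels do not give the sex of the mice. Of 100 splits of the 16 libraries, 2 gave as many genes, the real one included, and the highest other gave 800 genes. Splits that mix the genotypes turn the knockout effect into spread within groups, so this count does not decide whether chance can be excluded.

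In the groups of 4 libraries, 4 named genes had 1 library far from the other 3, of 120 gene and group pairs tested, where chance gives about 1 in 20 (6). They are Aars in RISP_WT replicate 2 (153 against 146 to 147), Serpina3g in RISP_Chimera_WT replicate 4 (69.0 against 41.6 to 42.5), Myo3b in RISP_Chimera_WT replicate 4 (26.9 against 16.3 to 17.5) and Irf4 in RISP_Chimera_WT replicate 4 (92.3 against 79.1 to 80.9), in CPM. Of these, 3 are in RISP_Chimera_WT replicate 4.

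With 3-NPA and antimycin A, effects on RNAs of mitochondrial DNA tended to be more negative further along the heavy-strand transcript. A single factor for all mitochondrial transcripts, such as a lower share of mitochondrial RNA, is argued against by mt-Rnr1 and mt-Cytb, whose log2 fold changes lie 4.80 apart with 3-NPA and 5.06 apart with antimycin A. A change of ribosomal against messenger RNAs alone, equal for all mRNAs, is argued against by mt-Nd1 and mt-Cytb, the first and last measured. Their log2 fold changes were -0.41 ± 0.10 and -2.59 ± 0.12 (SE) with 3-NPA, and -0.70 ± 0.10 and -2.87 ± 0.12 with antimycin A. For the 6 heavy-strand mRNAs the rank correlation with position was -0.89 with each inhibitor (exact permutation p = 0.0333, n = 6 genes, adjusted p = 0.049995 over the 18 tests of this kind). Over all 8 genes it was -0.95. Such p-values treat genes of 1 transcript as independent and do not measure the spread between libraries. In vitro, 7 of the 13 listed mitochondrial mRNAs were measured. Lower output along the transcript cannot be judged from the ribosomal RNAs. mt-Rnr1 and mt-Rnr2 rose with both inhibitors, the lowest of the 4 log2 fold changes being 1.01 ± 0.09 (SE, mt-Rnr2 with antimycin A). After poly(A) selection, counts also depend on the poly(A) tails of these RNAs, which were not measured. The highest log2 fold change of the mRNAs was -0.41 (mt-Nd1 with 3-NPA). For them, lower output cannot be told apart from faster decay, because the fall is what prompted the idea and no separate test was made. Reads shared with nuclear copies of mitochondrial DNA were not tested.

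G2 and M phase genes had a median log2 fold change of 1.04 in RISP_Chimera_KO, with Cenpe as the 1 called gene. A single library does not carry it: the lowest median without 1 library was 0.88, without RISP_Chimera_KO replicate 2, and the list was called each time. RNA of B cells, plasma cells and macrophages is argued against as the whole cause by a median of 0.72 with their markers as a covariate. There the list was still called. Dendritic and natural killer cell markers, with medians of 0.92 and 0.64 in RISP_Chimera_KO, are not in that covariate. RNA of cell types outside it was not tested. More cycling cells in the knockout cannot be told apart from other causes, since the S phase genes had a median of 0.17, called with the preset correlation (adjusted p = 1.87e-04) and not with the estimated one (0.530). The knockout itself stays a hypothesis for this pattern, which was lost as a list call with the estimated correlation (adjusted p = 0.247). In RISP_KO the same list pointed up too, with 25 of 25 log2 fold changes positive. Its median there was 0.34 (camera adjusted p = 1.25e-04, adjusted p = 0.625 with the estimated correlation).

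Foxp3 read 24.4 to 38.1 CPM in the 8 libraries of the 3-week-old table, against 386 to 508 CPM in chimeras and 516 to 825 CPM in vitro. A drop of all Treg identity genes as large as that of Foxp3 is argued against by the other 19. Their median log2 ratio of RISP_WT to RISP_Chimera_WT was 0.17 (-1.20 to 1.90). This ratio spans another kit and age, so it does not decide whether fewer of the sorted cells were Treg cells. The library kit each label names (log2 ratio of Foxp3 -3.75 to RISP_Chimera_WT) and the age of the mice (-4.03 to Untreated, also of 3-week-old mice but cultured and of the other kit) cannot be told apart, because no other group shares that kit or is uncultured at that age. The reporter allele, whose form the labels do not give for each table, stays open as well and was not tested.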

How the results depend on the processing

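The fits with markers of other cell types, the chimera fit without 2 knockout libraries and the correlations without 1 library were chosen after seeing the data, and the other alternatives were planned. The cause of each change given here was not tested.

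With DESeq2 the counts of called genes were 2068 for RISP_KO, 446 for RISP_Chimera_KO and 854 for the difference of knockout effects, and within 1.5 times the edgeR count for the 6 in vitro comparisons. Without a filter on low counts, 208 genes were called in RISP_Chimera_KO. The filter of 1 CPM, RLE factors and fits of only the 2 groups compared left every gene count within 1.5 times. With a 1.5-fold minimum, which can only remove genes, the counts were 905 for RISP_KO, 786 for piericidin, 163 for 3-NPA, 930 for antimycin A, 251 for antimycin A against 3-NPA and 289 for piericidin against 3-NPA.

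Replicate numbers were checked as pairs: same-numbered in vitro libraries had residual correlations of 0.004 to 0.090, under the 0.1 set for pairing, and those of the 2 in vivo tables were -0.102 to 0.127. Of 12 in vitro libraries, 12 correlated best with their own number in other groups, against 2 of 8 in chimeras and 0 of 8 in 3-week-old mice. In vitro the mean was 0.039 for the same number and -0.020 for other numbers, so a weak structure by number exists that the main fit leaves out. With the replicate block, 895 genes were called in RISP_KO and 324 for the difference of knockout effects. In vitro it gave 1733 with piericidin and 481 with 3-NPA.

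With markers of other cell types as a covariate the counts were 107 in RISP_KO, where the markers part the genotypes, and 183 in RISP_Chimera_KO, which had 247 without its replicates 2 and 4.

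Without 1 library at a time, the counts ranged from 787 to 1486 for RISP_KO, 33 to 177 for RISP_Chimera_KO, 1009 to 1421 for piericidin, 130 to 295 for 3-NPA, 1261 to 1613 for antimycin A, 43 to 75 for antimycin A against piericidin, 188 to 454 for antimycin A against 3-NPA, 230 to 409 for piericidin against 3-NPA and 323 to 627 for the difference of knockout effects. The number of lists called ranged from 13 to 22 in 3-NPA vs Untreated and 8 to 17 in AntimycinA vs Piericidin.

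With the estimated correlation, the lists called numbered 1 in RISP_KO, 0 in RISP_Chimera_KO, 8 with piericidin, 3 with 3-NPA, 10 with antimycin A, 2, 6 and 4 for antimycin A against piericidin, antimycin A against 3-NPA and piericidin against 3-NPA, and 0 for the difference of knockout effects. The other alternatives except leaving out 1 library kept each number of lists within 1.5 times.

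Among genes with a mean log2 CPM of at least 3, the correlation of the 2 knockouts was 0.274, that of RISP_KO -0.197 with piericidin and -0.198 with antimycin A, and that of RISP_Chimera_KO 0.111 with piericidin, 0.0555 with 3-NPA and 0.0185 with antimycin A, the last 2 with their sign reversed (3-NPA from a value within its spread between libraries). By Spearman, RISP_KO and antimycin A had -0.175, RISP_Chimera_KO and piericidin 0.0959, and RISP_Chimera_KO 0.0254 with 3-NPA and 0.00614 with antimycin A, both also reversed. The spread of a correlation between libraries was itself taken from the values without 1 library. Those values therefore give no separate test of it.

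Of 150 log2 fold changes named in the text, 96 kept their direction and their side of the threshold under every alternative run, and of 75 list tests 26. Of these, only the macrophage list in RISP_Chimera_KO reversed, uncalled, with a median of -0.14 under the covariate, which holds its markers, and -0.19 without replicates 2 and 4. Not every list test and log2 fold change given in the text is among those 75 and 150. Uqcrfs1 stayed called in RISP_KO and RISP_Chimera_KO under each alternative. The in vitro comparisons tested 11689 genes, and the knockout comparisons 13832 and 14399.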

Other observations

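The order of Uqcrfs1 among in vitro libraries was chosen for mention after the values were seen, and the splits of the libraries were planned.

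Splits of the 8 libraries of 3-week-old mice into 4 and 4 gave as many called genes in 1 of 35, the real one. It gave 1364 genes, against 1 in the highest other. For the chimeras, 1 of 35 splits gave as many, the real one, with 102 genes against 8. The other splits mix the genotypes, which turns the knockout effect into spread within groups. Neither count therefore decides whether chance can be excluded. With 3 libraries per group there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1584 and 0 for piericidin, 377 and 0 for 3-NPA, 1754 and 0 for antimycin A, 86 and 5 for antimycin A against piericidin, 465 and 0 for antimycin A against 3-NPA, and 502 and 1 for piericidin against 3-NPA. In each, 1 of 10 splits gave as many genes, the real one.

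Uqcrfs1 was highest in replicate 2 of all 4 in vitro groups, at 104 CPM in Untreated, 93.1 in Piericidin, 105 in 3-NPA and 74.4 in AntimycinA, against 42.9 to 70.1 CPM in the other 8 libraries.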
